A study of Mus musculus with 8 samples.

How the data were processed

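Gene expression was measured in whole tibialis anterior muscle of aged male C57BL/6 mice, 99 weeks old per the labels and 22 months old per the series' design text. The muscle had been injured by touching it with a metal probe cooled in liquid nitrogen for 8 s. Recombinant interleukin 33 (rIL-33, 2 µg per injection, into the peritoneal cavity) was given on the day before and on the day after the injury, or the mice carried the treatment label PBS. Muscles were taken at day 8 after injury, RNA was extracted with TriZol, and 1 biotin-labelled sample was hybridised to each Affymetrix Mouse Gene 1.0 ST array. There were 4 rIL-33 and 4 PBS arrays. In each group, replicates 1 and 2 carry the genetic background label C57BL/6 and replicates 3 and 4 the label WT; what separates these labels is not given in the sources used here.

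The deposited values are intensities of probe sets, made with the RMA method and Affymetrix Power Tools per the submitters' processing notes, with versions not given in the sources used here. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a probe set. The deposited intensities were on a linear scale, whereas log2 values had been foreseen, so log2 was taken first, as had been laid down for that case. Signal that does not come from the gene compresses the folds of dim probe sets, and a fold here is the ratio of geometric means of intensity. The value table held 24922 probe sets for each of the 8 arrays. In the platform annotation, 21425 of them had exactly 1 gene symbol, 1399 had several and 2098 were not listed. Probe sets with several symbols or none were left out of the gene tests. For each of the 19752 genes the probe set with the highest mean over all arrays was used. The 4938 genes with a mean under the 25th percentile (log2 intensity 6.65, intensity 100.4) were left out as dim, which left 14814 genes tested. Array data give no read depth, and the number of arrays limits the precision.

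Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on all 8 arrays with no block, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 differences are rIL-33 minus PBS and are given with the standard error (SE) of the limma fit; group levels are means ± SD of log2 intensity. The labels do not say that each array came from a mouse of its own, so p-values measure the spread between these samples. The script was tested on simulated data for this comparison with 14814 genes: it recovered 64% of 50 genes changed by 0.5 on the log2 scale, 98% of 50 changed by 1, and 100% of 50 each changed by 2 and by 3, with 9 false calls. Noise in the gene simulation was independent between genes, and many genes were changed at once, which eases the adjusted threshold. Its shares therefore do not tell how often such changes would be found here, where 1 gene passed. In a simulation without correlation between genes, the list test recovered the 1 shifted list and called 0 of the others.

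Before the data were examined, 29 gene lists were fixed, for cell types and for muscle, matrix and immune programmes, with 503 distinct genes, of which 461 were found in the values and 416 were tested. Lists with at least 5 tested members, 27 of them, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Beside it stand camera with a correlation estimated from the data, fry (which asks whether a list's genes move one way and does not compare them with other genes), and an exact two-sided permutation test of the list's mean level over the 70 assignments of the 8 arrays, whose smallest possible p is 0.0286. Some genes stand in several lists (Klrg1 and Gata3 in those of regulatory T cells and of type 2 cytokines, Mrc1 and Cd163 in both macrophage lists), so these lists are not independent. For the members of a list, p-values were also adjusted over the list alone.

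The genes named were set by a rule fixed in advance. It takes, per direction, the 10 genes of largest difference past the threshold, filled up to 10 with the genes of smallest p among those in which all 4 arrays of one group lay beyond all 4 of the other. In each list it adds the members past the threshold, or, with fewer than 2, up to the 2 members of largest difference, and it adds a set of genes of interleukin 33 signalling, regulatory T cells, regeneration and fibrosis whatever their values. Of this last set, 2 genes were not analysed here.

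The alternatives tried were quantile and cyclic loess normalization, no dim filter and one at the 50th percentile, eBayes with trend and robust, array weights, the replicate number or the genetic background label as a block, each label alone, the mean of a gene's probe sets, each array left out in turn, all probe sets, a threshold of 0.1, camera on ranks, camera with an estimated correlation, and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.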

Results

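Whole tibialis anterior muscle was profiled at day 8 after cryoinjury in aged mice given rIL-33 (4 arrays) or PBS (4 arrays). Interleukin 33 is an alarmin cytokine that acts on regulatory T cells, group 2 innate lymphoid cells and mast cells. The comparison asks how rIL-33 around the time of injury changed gene expression in regenerating aged muscle. Each array held 24922 probe sets, with a median intensity between 222.6 and 232.2.

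The arrays differed more by genetic background label than by treatment. The first principal component held 42.3% of the variance and the second 30.4%. On the first, the 4 arrays labelled C57BL/6 lay between 4.93 and 21.9 and the 4 labelled WT between -21.7 and 2.39, while PBS and rIL-33 arrays overlapped. The lower quartile of intensity was 88.3 to 93.8 on the C57BL/6-labelled arrays and 97.1 to 107.3 on the WT-labelled ones. Each treatment group held 2 arrays of each label, so values within each label are given beside the pooled ones for Retnla, for the lists past the threshold, and for other genes and lists whose treatment effect differed between the labels at an unadjusted p under 0.05 (11 of 87 named genes) or at a camera adjusted p under 0.05. Where leaving out 1 array moved a named gene's log2 difference of at least 0.5 by over 1.5 times (8 genes), the value without that array is given as well.

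**Figure D1:**
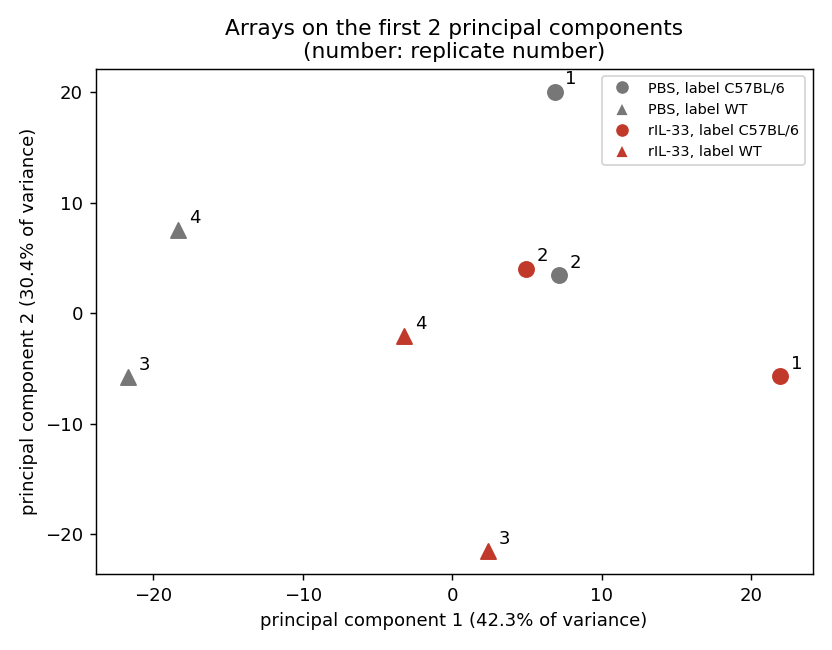
Positions of the 8 arrays on the first principal component (x axis, 42.3% of variance) and the second (y axis, 30.4%), with colour for treatment, shape for genetic background label and the replicate number beside each point. The WT-labelled arrays (triangles) lie to the left of the C57BL/6-labelled ones (circles).

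Retnla rose in the rIL-33 muscles and was the 1 gene past the threshold. It encodes RELMα (FIZZ1), a secreted protein made by alternatively activated macrophages and induced by interleukin 4 and interleukin 13. Its level (probe set 10436095) was 7.89 ± 0.46 with PBS and 10.63 ± 0.41 with rIL-33 (log2 intensity, SD, n = 4 per group), a 6.69-fold difference. The log2 difference was 2.74 (SE 0.24, limma adjusted p = 0.00568), and all 4 rIL-33 arrays lay above all 4 PBS arrays. Retnla was higher by 2.38 within the C57BL/6-labelled arrays and by 3.11 within the WT-labelled ones, with an adjusted p of 0.00571 in limma with the label as a block. Within the C57BL/6-labelled arrays alone it was not past the threshold (limma adjusted p = 0.126).

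No gene was lower past the threshold, and the second smallest adjusted p in limma was 0.305. At an unadjusted limma p under 0.05 there were 651 genes higher and 776 lower with rIL-33, together 1427 of 14814, where chance gives 740.7 on average. This total was 638 without rIL-33 replicate 1, 2244 with the genetic background label as a block and 2327 with the replicate number as a block. Groups without overlap were seen in 361 genes higher and 316 lower, 4.57% of the genes, where chance gives 2.86% on average. The 8 arrays can be split into groups of 4 in 34 other ways, the one by genetic background label among them. Of these, 6 had more genes at p under 0.05 than the treatment and 6 had more genes without overlap. Splits not balanced for the label also carry part of the label difference. Of the 18 splits with 2 arrays of each label per group, 1 had more genes at p under 0.05 than the treatment and 2 had more without overlap. Those 18 are too few for a share under 0.05, so neither count alone is evidence of a treatment effect.

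Below Retnla, the higher genes with the smallest p and no overlap between the groups did not pass the threshold (limma adjusted p between 0.305 and 0.489). Klrg1, a receptor on activated T cells and innate lymphoid cells, was higher by 0.60 on the log2 scale (SE 0.11). Gata3, the transcription factor of type 2 lymphocytes, was higher by 0.34 (SE 0.08). Their PBS means, 6.52 and 6.62, lay under the dim cut-off of 6.65, so both were tested only because the rIL-33 arrays raised the mean. Zbtb16, which encodes the transcription factor PLZF, was higher by 0.47 (SE 0.10). The interferon-inducible GTPase gene Gbp4 was higher by 1.16 (SE 0.26), with 0.55 within the C57BL/6-labelled and 1.76 within the WT-labelled arrays. Fgf6, a fibroblast growth factor of muscle, differed by 0.34 (SE 0.08), and F7, coagulation factor VII, by 0.53 (SE 0.12; 0.79 within C57BL/6 and 0.28 within WT). The largest of these differences was that of Snord118, the U8 small nucleolar RNA, at 1.79 (SE 0.28). Sel1l3 and Rprd1a, the remaining genes of this set, differed by 0.43 (SE 0.10) and 0.31 (SE 0.07).

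The lower genes with the smallest p and no overlap did not pass the threshold either (limma adjusted p between 0.305 and 0.489). Dlk1, an imprinted gene of fetal and regenerating tissue, was at 10.04 ± 0.28 with PBS and differed by -1.04 (SE 0.18) with rIL-33. Plagl1, an imprinted zinc finger transcription factor gene, differed by -0.87 (SE 0.13). Both angiotensin II receptor genes of the set were lower, Agtr2 by -0.85 (SE 0.14) and Agtr1a by -0.44 (SE 0.08). Lumican (Lum), a proteoglycan of collagen fibrils, differed by -0.76 (SE 0.15), and the microfibril protein gene Mfap4 by -0.58 (SE 0.12). Cx3cr1, the fractalkine receptor of monocytes and macrophages, differed by -0.38 (SE 0.07), and the purinergic receptor gene P2ry13 by -0.52 (SE 0.10). Midkine (Mdk) and the glycosyltransferase gene Glt8d2 both differed by -0.43 (SE 0.09).

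**Figure D2:**
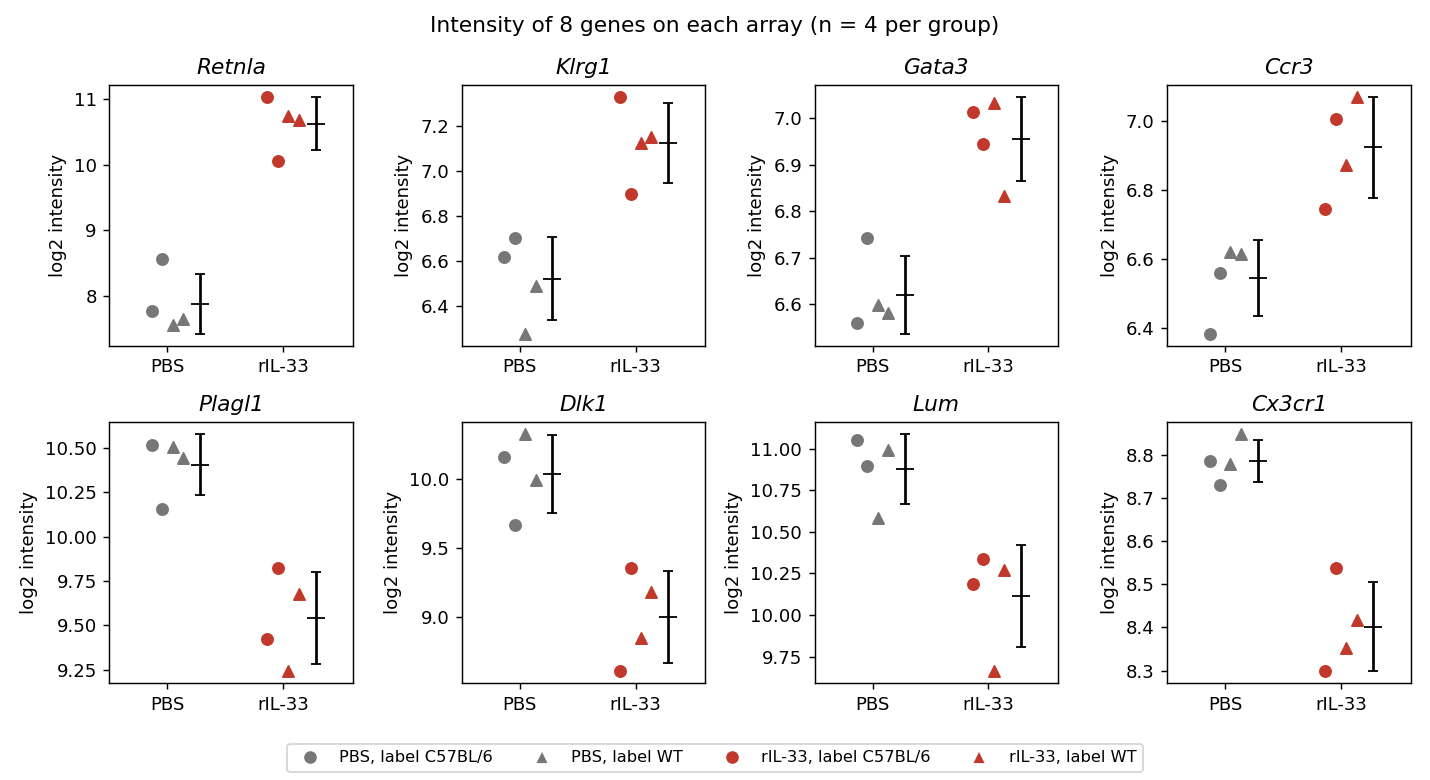
Log2 intensity (y axis) of 8 genes on each array by treatment (x axis), with bars for mean ± SD (n = 4 per group) and shapes for genetic background label. Retnla (7.89 to 10.63) passed the threshold, and the other genes shown did not, although their groups do not overlap.

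Genes of interleukin 33 signalling, regulatory T cells and muscle regeneration that had been chosen in advance did not pass the threshold where tested. Il1rl1 and Areg, of the same set, were not among the genes with a value, so nothing is known of them here. Il33 itself differed by -0.28 (SE 0.15) and its co-receptor gene Il1rap by -0.22 (SE 0.14). Foxp3, the transcription factor that defines regulatory T cells, was 7.35 ± 0.18 with PBS and 7.29 ± 0.19 with rIL-33, a difference of -0.05 (SE 0.12). Ikzf2 (Helios) differed by 0.24 (SE 0.10) and the leukocyte antigen gene Ptprc (CD45) by -0.19 (SE 0.13). The type 2 cytokine gene Il13 differed by -0.13 (SE 0.13), and Il5 was left out as dim (5.91 with PBS, 6.13 with rIL-33). Of the myogenic regulators, Pax7 differed by -0.02 (SE 0.11), Myod1 by -0.11 (SE 0.13) and Myog by -0.22 (SE 0.19). The embryonic and neonatal myosin genes Myh3 and Myh8 differed by -0.04 (SE 0.19) and -0.05 (SE 0.16), and the fast myosin gene Myh4 by 0.10 (SE 0.08). The collagen genes Col1a1 and Col3a1 differed by -0.36 (SE 0.13) and -0.38 (SE 0.12), and the adipocyte gene Adipoq by -0.04 (SE 0.12).

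Among the 27 lists tested, camera with the preset correlation placed 17 past its threshold, 5 higher and 12 lower with rIL-33. None passed with an estimated correlation (smallest adjusted p = 0.310, with 3 lists at an unadjusted p under 0.05), none in fry (adjusted p between 0.188 and 0.561) and none in the exact permutation test after adjustment (smallest adjusted p = 0.309). Before adjustment, the exact permutation p was under 0.05 in 2 lists, those of alternatively activated macrophage genes and of type 2 cytokines. In the other lists past camera's threshold the exact permutation p lay between 0.0571 (fibro-adipogenic progenitors) and 0.486 (oxidative phosphorylation). With the genetic background label as a block, 17 lists were past the threshold at the preset correlation and 0 at an estimated one. In 14 of the 17 the sign was one and the same within both labels. Except for Retnla, no member of any list passed the threshold over all genes.

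Alternatively activated macrophage genes were higher as a list, by a mean log2 of 0.31 and a median of 0.08 over 12 members (camera adjusted p = 0.00918). The adjusted p was 0.310 with an estimated correlation, and the exact permutation p was 0.0286, the smallest possible. Members higher with rIL-33 numbered 8, and 1, Retnla, passed when adjusted over the list alone. Mgl2, a lectin receptor of these macrophages, differed by 0.37 (SE 0.13), but by 0.07 within the C57BL/6-labelled and 0.67 within the WT-labelled arrays. Without Retnla, an alternative chosen after seeing the data, the list's mean was 0.08 and the call was lost (camera adjusted p = 0.129). The mean was 0.25 within the C57BL/6-labelled and 0.36 within the WT-labelled arrays.

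The list of type 2 cytokines and ILC2 was higher by a mean of 0.15 with a median of 0.03, 7 of 11 members being higher (camera adjusted p = 0.0112). With an estimated correlation the adjusted p was 0.310, and the exact permutation p was again 0.0286. Klrg1, Gata3 and Il17rb, the interleukin 25 receptor, were the 3 members past the threshold when adjusted over the list alone. All 3 were near the dim cut-off of 6.65 with PBS, Klrg1 (6.52) and Gata3 (6.62) under it. Il17rb stood at 6.66 with PBS and 7.01 with rIL-33. The interleukin 7 receptor gene Il7r differed by 0.44 (SE 0.20). The list's mean was 0.21 within the C57BL/6-labelled and 0.08 within the WT-labelled arrays. Its call was lost without PBS replicate 1 (mean 0.12, camera adjusted p = 0.0843) or without PBS replicate 2 (0.13, camera adjusted p = 0.0588). Of the eosinophil list only 3 members were tested: Ear1 and Ear2 were not among the genes with a value, and the others were dim. The chemokine receptor gene Ccr3 differed by 0.38 (SE 0.09) and Alox15, a lipoxygenase, by 0.50 (SE 0.16). Both were higher on all rIL-33 arrays than on all PBS arrays and passed the threshold when adjusted over the list alone. Ccr3 stood at 6.55 with PBS, under the dim cut-off, and at 6.92 with rIL-33. The remaining tested member, Siglecf, named here after its value was seen, differed by -0.03 (SE 0.14), and the granule protein genes Epx, Prg2 and Prg3 were dim.

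Lists of matrix and stromal genes were lower with rIL-33. All 28 extracellular matrix and fibrosis genes were lower, by a mean of -0.40 (camera adjusted p = 2.57e-16, but adjusted p = 0.394 with an estimated correlation). The mean was -0.29 within the C57BL/6-labelled arrays and -0.50 within the WT-labelled ones, and 15 members passed when adjusted over the list alone. Lum (-0.76, SE 0.15) and the fibril-associated collagen gene Col12a1 (-0.73, SE 0.27; -0.48 without rIL-33 replicate 3) differed most. All 14 genes of fibro-adipogenic progenitors, the mesenchymal cells of muscle, were lower by a mean of -0.26 (camera adjusted p = 1.27e-06, adjusted p = 0.310 with an estimated correlation). Within the labels the means were -0.30 (C57BL/6) and -0.23 (WT), and 5 members passed when adjusted over the list alone. Dermatopontin (Dpt) differed by -0.61 (SE 0.15) and Mfap5, a microfibril gene, by -0.53 (SE 0.14). The endothelium list was lower by -0.11, in 12 of 15 members (camera adjusted p = 0.00149, adjusted p = 0.394 with an estimated correlation), and by -0.13 and -0.10 within the C57BL/6 and WT labels. Its largest differences were those of endoglin (Eng, -0.33, SE 0.10) and endomucin (Emcn, -0.32, SE 0.08), and Emcn passed when adjusted over the list alone.

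Proliferation genes moved in the same direction. All 37 cell cycle genes were lower, by a mean of -0.28 (camera adjusted p = 7.12e-15, adjusted p = 0.394 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. Cyclin genes Ccna2 and Ccnb2 differed by -0.58 (SE 0.18) and -0.56 (SE 0.15). The list's mean was -0.21 within the C57BL/6-labelled arrays and -0.35 within the WT-labelled arrays.

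Several leukocyte lists were lower as well. Macrophage genes had a mean of -0.23, with 16 of 19 lower (camera adjusted p = 9.76e-06, adjusted p = 0.512 with an estimated correlation). The 2 members past the threshold when adjusted over the list alone were Cx3cr1 and Ms4a7. Ms4a7 differed by -0.60 (SE 0.17) and the Fc receptor gene Fcgr1 by -0.55 (SE 0.17), and the list's means were -0.25 and -0.21 within the C57BL/6 and WT labels. All 14 T cell genes were lower by a mean of -0.31, with 0 past the threshold when adjusted over the list alone (camera adjusted p = 1.03e-05, adjusted p = 0.394 with an estimated correlation). The T cell receptor complex gene Cd3g differed by -0.88 (SE 0.46; -0.58 without PBS replicate 1, -0.59 without rIL-33 replicate 1) and Cd8b1 by -0.68 (SE 0.28, or -0.45 without PBS replicate 1), and the list by -0.41 and -0.22 within the C57BL/6 and WT labels. NK and cytotoxic cell genes differed by -0.36, with 11 of 12 lower and 0 past the threshold when adjusted over the list alone (camera adjusted p = 8.60e-05, adjusted p = 0.394 with an estimated correlation). This mean was -0.70 within the C57BL/6-labelled arrays and -0.01 within the WT-labelled ones, and Ccl5 differed by -0.91 (SE 0.26) and the granule gene Nkg7 by -0.80 (SE 0.38). Within the C57BL/6 and WT labels Ccl5 differed by -1.41 and -0.41 and Nkg7 by -1.41 and -0.19, and without PBS replicate 1 Nkg7 differed by -0.47.

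Inflammatory myeloid genes were lower in all 9 members, by a mean of -0.49 (camera adjusted p = 0.000266, adjusted p = 0.394 with an estimated correlation), by -0.30 and -0.68 within the C57BL/6 and WT labels. Interleukin 1 beta (Il1b) differed by -1.38 (SE 0.54) and the cyclooxygenase gene Ptgs2 by -0.90 (SE 0.25), and Ptgs2 was the 1 member past the threshold when adjusted over the list alone. Il1b stood at 9.86 in PBS replicate 4 and between 7.06 and 7.11 in the other PBS arrays, and without that array Il1b differed by -0.68 and the list's mean was -0.27 and stayed past the threshold. Neutrophil genes were lower by -0.59 in all 6 members tested, with 0 past the threshold when adjusted over the list alone (camera adjusted p = 0.00918, adjusted p = 0.512 with an estimated correlation). The other members of this list were dim, and of those Retnlg alone was higher with rIL-33, by 0.34. Both WT-labelled PBS arrays were high in this list, so that its mean difference was 0.05 within the C57BL/6-labelled and -1.22 within the WT-labelled arrays. Without PBS replicate 4 it was -0.20 and the call was lost (camera adjusted p = 0.115). The granule protein gene Ngp differed by -0.94 (SE 0.62), with 0.24 within C57BL/6, -2.11 within WT, -0.33 without PBS replicate 3 and -1.44 without PBS replicate 1. Ngp and Il1r2 lay under the dim cut-off with rIL-33, at 6.23 and 6.53. The gelatinase gene Mmp9 differed by -0.64 (SE 0.25), with -0.15 within C57BL/6, -1.12 within WT and -0.39 without PBS replicate 4.

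Antigen presentation and dendritic cell genes differed by a mean of -0.10, with 11 of 16 lower (camera adjusted p = 0.0200, adjusted p = 0.525 with an estimated correlation). Their members did not move as a block. The migratory dendritic cell receptor gene Ccr7 differed by -0.53 (SE 0.11) and the integrin gene Itgax (CD11c) by 0.55 (SE 0.22). When adjusted over the list alone 5 members passed, Ccr7 among them, all of them lower. Itgax did not pass there (limma p adjusted over the list alone = 0.0793). The mean was -0.26 within the C57BL/6-labelled and 0.05 within the WT-labelled arrays, and the call was lost without PBS replicate 1 (-0.07), without PBS replicate 4 (-0.07) or without rIL-33 replicate 2 (-0.07). Without PBS replicate 3 or rIL-33 replicate 4 it was -0.18 and -0.16. Immediate early and heat shock genes differed by -0.16, with 12 of 15 lower and 0 past the threshold when adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.512 with an estimated correlation). Fos and Egr1 differed by -0.58 (SE 0.21) and -0.44 (SE 0.21). This list's mean was -0.30 and -0.03 within the C57BL/6 and WT labels, and its call was lost without PBS replicate 1 (-0.13) or PBS replicate 2 (-0.10).

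Genes of mature muscle were slightly higher with rIL-33. Mature fast fibre genes were higher by a mean of 0.10, in 23 of 26 members (camera adjusted p = 9.41e-05, adjusted p = 0.512 with an estimated correlation), by 0.06 and 0.15 within the C57BL/6 and WT labels. Cacna1s, the calcium channel of the T tubule, differed by 0.24 (SE 0.10) and the fibre repair gene Xirp2 by 0.21 (SE 0.10). All 15 glycolysis genes were higher, by a mean of 0.16 (camera adjusted p = 0.000250, adjusted p = 0.525 with an estimated correlation), by 0.05 and 0.27 within the C57BL/6 and WT labels. Without PBS replicate 4 the means were 0.07 in fast fibres and 0.10 in glycolysis, both still past the threshold. Hexokinase 2 (Hk2) differed by 0.33 (SE 0.13) and the phosphorylase kinase gene Phkg1 by 0.34 (SE 0.20). Oxidative phosphorylation genes were higher by 0.10 in 41 of 44 members (camera adjusted p = 0.000745, adjusted p = 0.588 with an estimated correlation), but by -0.01 within the C57BL/6-labelled and 0.20 within the WT-labelled arrays. This call was lost without PBS replicate 4 (0.02) or without rIL-33 replicate 1 (0.03), the mean was 0.04 without PBS replicate 3 and 0.16, 0.17 and 0.16 without PBS replicate 1, PBS replicate 2 and rIL-33 replicate 4, and the complex I genes Ndufa5 and Ndufb3 differed by 0.30 (SE 0.16) and 0.22 (SE 0.14). In these 3 lists, 0 members passed when adjusted over the list alone.

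Myogenic differentiation and immature fibre genes were lower by a mean of -0.15 and a median of -0.08, in 15 of 16 members (camera adjusted p = 0.0209, adjusted p = 0.588 with an estimated correlation). Dlk1 (-1.04, SE 0.18) differed most and was the 1 member past the threshold when adjusted over the list alone, followed by Myog (-0.22, SE 0.19). The list's mean was -0.12 within the C57BL/6-labelled and -0.17 within the WT-labelled arrays. Its call was lost without PBS replicate 1 (-0.09), without rIL-33 replicate 1 (-0.12) or without rIL-33 replicate 3 (-0.06), and the mean was -0.24 without rIL-33 replicate 2.

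The other 10 lists did not pass in camera, with adjusted p between 0.197 and 0.906. The regulatory T cell list differed by a mean of 0.04, with 7 of 13 members higher. Its 2 members past the threshold when adjusted over the list alone were Klrg1 and Gata3. Both also belong to the type 2 list and lay under the dim cut-off with PBS. Lrrc32 (GARP), a surface protein of activated regulatory T cells, differed by -0.34 (SE 0.13). Satellite cell genes differed by -0.02 (-0.09 within C57BL/6, 0.04 within WT) with 6 of 15 higher, among them Chodl (0.20, SE 0.15), while the signalling inhibitor gene Spry1 differed by -0.17 (SE 0.15), by -0.42 and 0.08 within the C57BL/6 and WT labels. Slow fibre genes (-0.02; 0.17 within C57BL/6, -0.22 within WT) held Csrp3 at -0.45 (SE 0.22) and Myl3 at 0.27 (SE 0.25). The atrophy and denervation list (mean -0.02, median 0.02, -0.15 and 0.11 within the C57BL/6 and WT labels) held Runx1 at -0.30 (SE 0.14) and the metallothionein gene Mt2 at -0.20 (SE 0.18). Interferon response genes had a mean of 0.02, with -0.18 within C57BL/6 and 0.22 within WT. Gbp3 differed by 0.50 (SE 0.18; 0.18 and 0.82 within the 2 labels, 0.31 without rIL-33 replicate 3) and Cxcl9 by 0.25 (SE 0.39; -0.53 and 1.03). Senescence genes had a mean of -0.01, with the macrophage elastase gene Mmp12 at 0.93 (SE 0.42) and stromelysin 1 (Mmp3) at -0.46 (SE 0.20).

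Mast cell genes had a mean of -0.12, with Cpa3 at -0.38 (SE 0.25) and the protease gene Mcpt4 at -0.33 (SE 0.22), which within C57BL/6 differed by -0.76 and -0.61 and within WT by -0.0020 and -0.05. B and plasma cell genes had a mean of -0.06 (0.01 within C57BL/6, -0.14 within WT), with Cd22 and Cd79b at -0.19 (SE 0.09) and -0.18 (SE 0.09). Adipocyte genes had a mean of 0.06, with Plin4 at 0.26 (SE 0.12) and the lipoprotein lipase gene Lpl at 0.23 (SE 0.14). The Schwann cell and nerve list had a mean of 0.04, with the myelin genes Mbp and Mag at 0.14 (SE 0.07) and 0.11 (SE 0.11). Apart from regulatory T cells, 0 members of these 10 lists passed when adjusted over the list alone. Of the red blood cell list, 2 members could be tested, too few for a test of the list. Slc4a1 differed by -0.31 (SE 0.23) and Alas2 by -0.02 (SE 0.14). The sign of Alas2 turned after cyclic loess normalization (0.01).

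**Figure D3:**
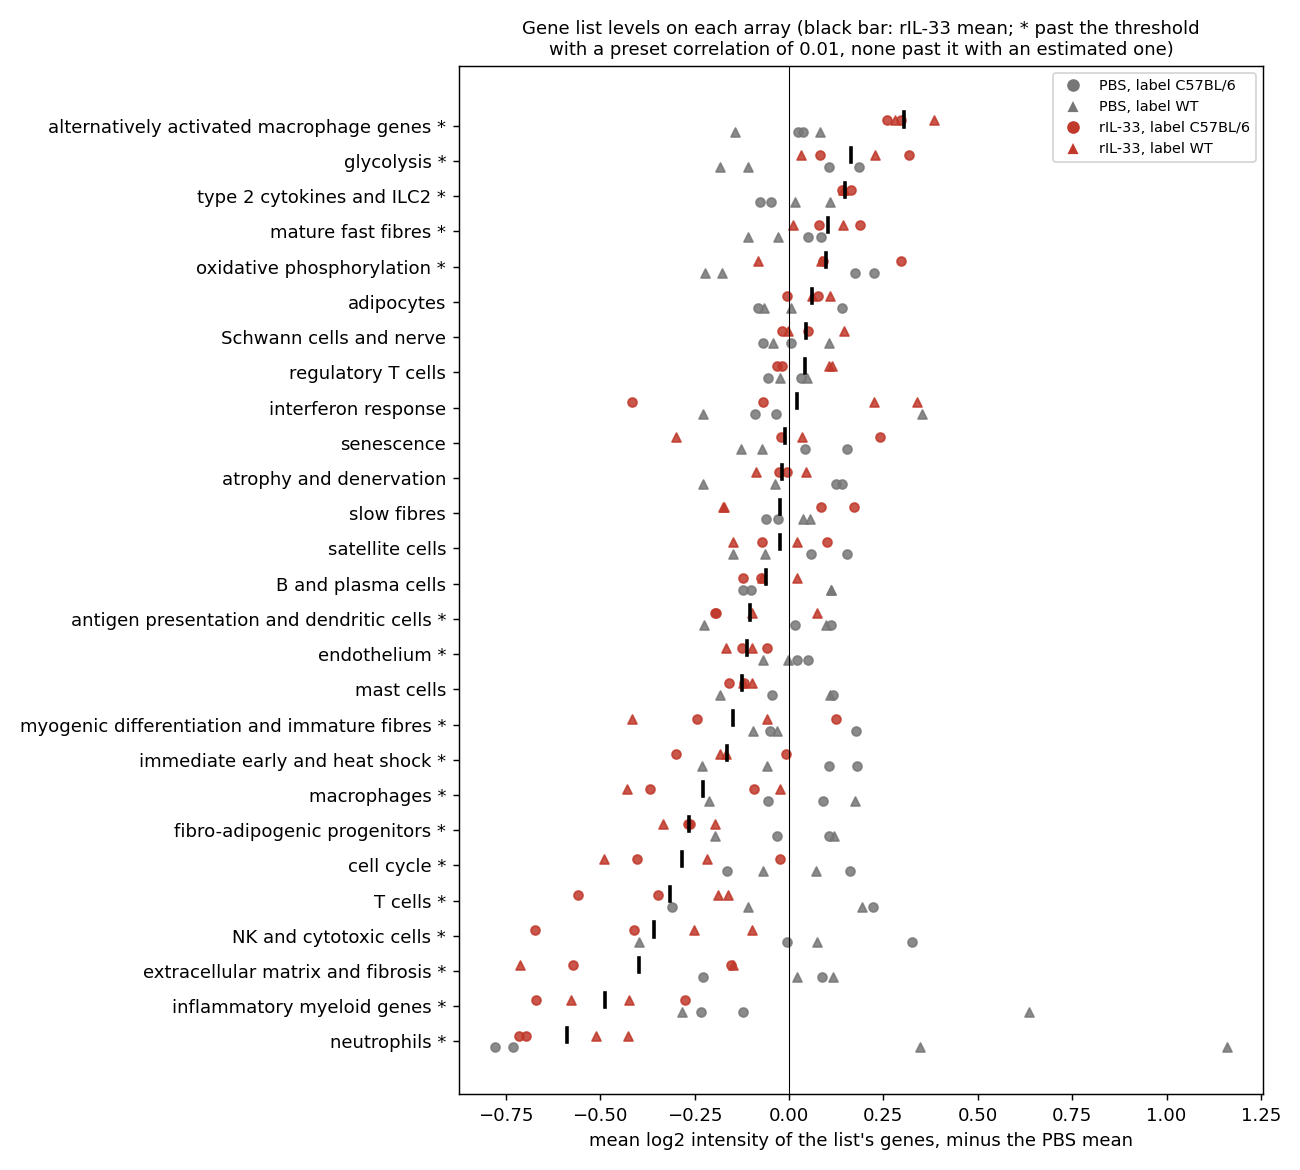
Mean log2 intensity of each list's genes on each array minus the PBS mean (x axis) for the 27 lists tested (y axis), with colour for treatment, shape for genetic background label and a black bar for the rIL-33 mean. Asterisks mark the 17 lists past the threshold of camera with a preset correlation of 0.01, of which 0 passed with an estimated correlation; rIL-33 means run from -0.59 (neutrophils) to 0.31 (alternatively activated macrophage genes).

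The genetic background labels themselves separated more genes than the treatment. With treatment in the limma fit, 1392 genes passed the threshold between the labels, 919 lower and 473 higher on the WT-labelled arrays. After quantile normalization, a setting added after the data were examined, 415 genes passed, 306 lower and 109 higher, and 365 of them were among the 1392. Of the 44 oxidative phosphorylation genes, 19 were lower and 0 higher on the WT-labelled arrays, and of 62 ribosomal protein genes 19 were lower and 0 higher; after quantile normalization these counts were 7 and 12 lower, with 0 higher in both. Small non-coding RNA genes went both ways, 23 lower and 21 higher of 183 (20 and 6 after quantile normalization). The last 2 groups were chosen after the data were examined. No gene passed the test of a difference in treatment effect between the labels in limma. At an unadjusted p under 0.05 there were 473, fewer than the 740.7 that chance gives on average.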

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

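The patterns weighed here were noticed in the data, and the tests of the label, of the resistin family, of the tissue share, of the distributions, of a linked region and of the splits balanced for the label were chosen after seeing the data. The first is the higher Retnla with rIL-33. An effect of the genetic background label is argued against by a log2 difference of at least 2.38 within each label. Signal from a related gene stays open: Retn differed by 0.11 (SE 0.15), but Retnlb and Retnlg, with the largest difference of the family at 0.336 (Retnlg, SE 0.16), were too dim for their values to exclude it. Of the 35 splits of the 8 arrays into groups of 4, 3 gave at least the 1 gene of the treatment, one of them the split by genetic background label with 796, the highest other count; this counts any gene, so it does not settle whether chance raised Retnla, which 1 split, the treatment, called and which was picked for that split. An effect of rIL-33 on alternatively activated macrophages may account for Retnla and remains a hypothesis: their list without Retnla had a mean of 0.084 and was not past the threshold (camera adjusted p = 0.129), and of its members, named after their values were seen, Mgl2 differed by 0.37 (SE 0.13; 0.07 within C57BL/6, 0.67 within WT), Cd163 by 0.27 (SE 0.11), Arg1 by -0.13 (SE 0.31) and Mrc1 by -0.22 (SE 0.15).

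The second pattern is the joint shift of the gene lists, with 17 lists past the threshold of camera at the preset correlation. Of all 35 splits, 1 (the treatment) reached 17 and the highest other count was 16, but the 18 splits that keep both labels balanced are too few for a share under 0.05, and with the label as a block 2 of these 18 reached 17, so chance stays open; the other splits called a median of 9 lists, so single calls at the preset correlation carry little weight. An effect of the genetic background label alone would cancel in the balanced design, and 17 lists stayed past the threshold with it as a block; 82.4% of the called lists had 1 sign within both labels, which leaves open that part of the shift belongs to 1 label. A smaller share of injured tissue in the rIL-33 muscles may also lower matrix, cell cycle and leukocyte genes and raise fibre genes. Of the genes of muscle regeneration, Myh3 differed by -0.04 (SE 0.19), Myh8 by -0.05 (SE 0.16) and the satellite cell list by -0.02. The myogenic differentiation list was lower by -0.15, in 15 of 16 members. Between arrays of a group the matrix and fast fibre lists varied oppositely (8 arrays, Pearson r = -0.737, exact permutation p = 0.0625; Spearman rho = -0.667, exact permutation p = 0.0625; r = -0.665 without the 2 farthest arrays; 1 relation computed), so a difference in tissue share and a treatment effect within cells cannot be told apart with 8 whole muscles.

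The third is the difference between the 2 genetic background labels. In a fit without treatment, the split by label called 796 genes and the highest other split 2. That is the first rank of 35 splits, the most extreme that 35 splits allow. The pattern was noticed in these data, so chance is argued against but not excluded. A linked region in which the mice differ, as the source of most of the called genes, is argued against by their spread. Chromosome 7 held the most, 8.73%. A region that holds a small part of the calls cannot be excluded by such a share. Distributions left unequal by the normalization may account for part of it: quantile normalization left 26.2% of the 1392 calls, and 415 genes were called after it, so this source and others (a batch of arrays, a substrain) cannot be told apart. No biological explanation was tested, since the sources used here do not say what separates the labels.

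Among 228 sets of 4 arrays, 2 had an array whose gap to the next exceeded Dixon's 95% critical value for 4 arrays, where chance gives 11.4. Il7r stood at 8.76 in rIL-33 replicate 3 against 9.65 to 9.76 in the other rIL-33 arrays (gap over range 0.899), and Il1b at 9.86 in PBS replicate 4 against 7.06 to 7.11 in the other PBS arrays (0.985).

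In 15 lists the treatment effect differed between the labels by camera's interaction test at the preset correlation, and in 0 with an estimated correlation. Given as the effect within WT minus that within C57BL/6, the differences were -1.27 in neutrophils, -0.39 in slow fibres, -0.38 in inflammatory myeloid genes, -0.21 in extracellular matrix and fibrosis, -0.15 in B and plasma cells and -0.14 in the cell cycle. On the other side they were 0.69 in NK and cytotoxic cells, 0.40 in the interferon response, 0.31 in antigen presentation and dendritic cells, 0.27 in immediate early and heat shock genes and 0.26 in atrophy and denervation. They were 0.22 in glycolysis, 0.21 in oxidative phosphorylation, 0.13 in satellite cells and 0.081 in mature fast fibres.

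Outside the gene tests, 5 probe sets that the platform annotation does not list passed the threshold over all probe sets, all higher with rIL-33 (limma adjusted p = 0.0395 each). Their log2 differences were 1.86 (probe set 10414262), 1.03 (10419151, dim at 4.36 with PBS and 5.38 with rIL-33, where differences are compressed), 1.48 (10419154), 1.62 (10419156) and 1.51 (10598175). Their deviations from the group means correlated in pairs at 0.13 to 1.00, so how many separate signals they are is open.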

How the results depend on the processing

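The list without Retnla, the test of treatment by label and the quantile normalization of the label comparison (415 genes against 1392) were chosen after seeing the data. Retnla kept its direction in all 19 alternatives (log2 2.38 to 3.11) and stayed past the threshold in 17 (limma adjusted p from 5.00e-05 to 0.126). It was lost within the C57BL/6-labelled arrays (2.38, adjusted p = 0.126, with 4 arrays) and with the replicate number as a block (2.74, adjusted p = 0.0778), a fit that leaves fewer degrees of freedom. Whether replicate numbers pair the arrays is not settled. Deviations of same-numbered arrays from their group means correlated at 0.44, -0.19, 0.43 and 0.54, so not every pair correlated, and 5 of 8 arrays correlated best with their own number. Same-numbered arrays also share a genetic background label, and these deviations still hold the label difference. Every array correlated best with an array of its own label, so these matches cannot tell pairing from the label. With the replicate block, 0 genes passed (0 higher), and of the lists antigen presentation alone was lost (-0.10, adjusted p = 0.0531). No setting moved the median of all genes by over 0.1.

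The count of genes was 6 (6 higher) over all probe sets, 2 (2 higher: Snord118 and Mmp12) within C57BL/6, and 4 (3 higher, 1 lower: BC023105, Gm4841, Retnla and Ppbp) within WT. Leaving out 1 array gave 1 to 2 genes (1 to 2 higher), 2 without rIL-33 replicate 4 (Snord118 and Retnla). The genes of these counts outside the naming rule were chosen after their values were seen.

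The list calls depended on the correlation between genes. With an estimated correlation 0 lists passed and with fry 0, at the same means: alternatively activated macrophage genes 0.31, glycolysis 0.16, type 2 cytokines 0.15, fast fibres 0.10, oxidative phosphorylation 0.10, antigen presentation -0.10, endothelium -0.11, myogenic differentiation -0.15, immediate early -0.16, macrophages -0.23, fibro-adipogenic progenitors -0.26, cell cycle -0.28, T cells -0.31, NK cells -0.36, matrix -0.40, inflammatory myeloid genes -0.49 and neutrophils -0.59. Of 355 values of called lists under alternatives, 287 stayed past the threshold in the same direction and 3 reversed. With the dim filter at the median, 10 of 18 lists tested passed. There 4 lists called otherwise had too few members to test (T cells, NK and cytotoxic cells, neutrophils and type 2 genes), and alternatively activated (0.48), antigen presentation (-0.041) and immediate early genes (-0.16) were lost. Camera on ranks lost alternatively activated (0.31), antigen presentation (-0.10) and type 2 genes (0.15). Antigen presentation was lost after quantile (-0.081) and cyclic loess normalization (-0.095), and array weights lost myogenic differentiation (-0.035) and oxidative phosphorylation (0.026). Without Retnla the alternatively activated list had a mean of 0.084 with either correlation. Within C57BL/6, neutrophils (0.048) and oxidative phosphorylation (-0.0057) reversed, and glycolysis (0.055) and myogenic differentiation (-0.12) were lost. Within WT, antigen presentation (0.052) reversed, and immediate early (-0.030), NK (-0.014) and type 2 genes (0.082) were lost. The cause was not tested, beyond the smaller number of arrays or genes in some settings.

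Leaving out 1 array at a time gave means of -0.18 to -0.066 for antigen presentation, -0.24 to -0.10 for immediate early genes, -0.24 to -0.059 for myogenic differentiation, 0.12 to 0.18 for type 2 genes, -0.85 to -0.20 for neutrophils (lost without PBS replicate 4) and 0.024 to 0.17 for oxidative phosphorylation, the 6 lists that lost their call in some of these fits. The lists of fast fibres (0.069 to 0.14) and glycolysis (0.10 to 0.23) kept theirs and were lowest without PBS replicate 4. Of 87 named genes, 39 moved by over 1.5 times or turned in sign without 1 array. Ranges crossing 0 were those of lists or genes not called: atrophy -0.095 to 0.029, interferon -0.086 to 0.17, satellite cells -0.074 to 0.028, senescence -0.096 to 0.085, slow fibres -0.088 to 0.028, Alas2 -0.14 to 0.084, Myh3 -0.19 to 0.14, Myh8 -0.17 to 0.12, Myod1 -0.21 to 0.0027, Pax7 -0.079 to 0.043, Adipoq -0.11 to 0.069, Foxp3 -0.11 to 0.019 and Cxcl9 -0.073 to 0.68.

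Values not called over all arrays reversed as follows. Array weights gave Alas2 0.064, Myh3 0.15, Myh8 0.093, Myl3 -0.030, Pax7 0.066, the interferon list -0.0019, satellite cells 0.023, senescence 0.061 and slow fibres 0.0040. Cyclic loess gave Alas2 0.0076, and no dim filter gave B and plasma cells 0.025. C57BL/6-labelled arrays alone gave Alas2 0.23, Cxcl9 -0.53, Myh3 0.16, Myh4 -0.0024, Myh8 0.081, Ngp 0.24, B and plasma cells 0.014, the interferon list -0.18 (past the threshold there, camera adjusted p = 0.00391), regulatory T cells -0.013, senescence 0.011 and slow fibres 0.17 (past the threshold there, camera adjusted p = 0.00321). In the direction they had over all arrays, lists newly past the threshold of camera were atrophy within C57BL/6 (-0.15), slow fibres (-0.22) and B and plasma cells (-0.14) within WT, the interferon list without rIL-33 replicate 1 (0.17) and Schwann cells without PBS replicate 3 (0.079). WT-labelled arrays alone gave Adipoq 0.14, Pax7 0.085, Spry1 0.084, atrophy 0.11 and satellite cells 0.042. Eosinophil genes could be tested only with no dim filter (mean 0.13, camera adjusted p = 0.0196). Array signal near background limits what can be said of dim genes such as Il5. The same holds for genes near the dim cut-off with PBS, such as Klrg1, Gata3, Il17rb and Ccr3. It also holds for lower genes under the cut-off with rIL-33, such as Ngp, Il1b, Il1r2, Klrd1, Klrk1, Eomes and Ncr1.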

Other observations

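Genes of the imprinted gene network and of tendon were looked at after Plagl1, Dlk1, Tnmd and Kera had been seen among the lower genes, so all tests in this part were chosen after seeing the data. Of 15 imprinted genes 12 were lower with rIL-33, by a mean log2 of -0.29, and all 4 rIL-33 arrays lay below all 4 PBS arrays (exact permutation p = 0.0286, the smallest possible). Besides Dlk1 and Plagl1, the noncoding RNA gene Meg3 differed by -0.73 (SE 0.22), Mest by -0.58 (SE 0.19) and Ndn by -0.37 (SE 0.10). Igf2 differed by -0.01 (SE 0.11), Peg3 by 0.02 (SE 0.14) and Slc38a4 by 0.24 (SE 0.09). Of 15 tendon genes 13 were lower, by a mean of -0.22 (exact permutation p = 0.0286), among them tenomodulin (Tnmd, -0.74, SE 0.17), Tppp3 (-0.47, SE 0.12) and keratocan (Kera, -0.46, SE 0.10). None of these genes passed the threshold in limma.

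That rIL-33 lowered the imprinted network as a group is a hypothesis. Without Plagl1 and Dlk1, whose values had been seen, the mean was -0.19 (-0.20 within C57BL/6, -0.18 within WT) with an exact permutation p of 0.2, so the data may or may not hold a shift of the other members. For tendon genes without Tnmd and Kera the mean was -0.16 (exact permutation p = 0.0857, 11 of 13 lower). Dlk1 and Igf2 also stand in the myogenic list, Egr1 in the immediate early list and Fmod in the matrix list, so neither shift is independent of those. A smaller share of injured tissue or of tendon in the dissected muscle could lower both lists and was not tested for them.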
